A study of Homo sapiens with 8 samples.

How the data were processed

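The series compared MDA-MB-231 cells, a human triple-negative breast cancer line, kept for 2 days on a soft or a stiff substrate. Total RNA of 4 biological replicates per substrate, lettered A to D, was hybridised to Affymetrix arrays, 1 array per replicate. The elastic modulus of either substrate was not given in the sources used here.

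The deposited values are log2 RMA summaries, 1 per probe set and array; RMA is named per the submitters' processing notes, and the log2 scale and the rounding to 2 decimals were read from the values themselves. RMA corrects background, equalises the distributions of the arrays and summarises the probes of a probe set, so it removes any shift common to all genes and compresses differences of dim probe sets. The RMA software, its version and the probe definition were not given in the sources used here. The table held 54675 probe sets. The manufacturer's 62 control probe sets were left out, which left 54613. Scanner files were not used here.

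Probe sets were named through the platform annotation, updated by gene identifier against a RefSeq gene table. A single symbol was found for 41091 probe sets, several for 1801 and none for 11721; probe sets with several symbols were not used for any gene. The 41091 probe sets named 19775 genes, and 10523 of these genes had more than 1 probe set. Each gene took the values and adjusted p of its probe set with the highest mean over the 8 arrays, a choice made without regard to the groups. Some items are not reported here, among them 2 of the 11 genes that had been chosen to be named whatever their result and 1 of the 34 gene lists with the genes that only it would have named, all of them still counted in adjustments and in counts of alternatives.

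Soft and stiff were compared with limma (version 3.58.1 in R 4.3.3): lmFit and eBayes without trend on the deposited log2 values of all 8 arrays, with Benjamini-Hochberg adjustment over the 54613 probe sets and a threshold of 0.05, no fold minimum and no filter on dim probe sets. Differences are soft minus stiff on the log2 scale, with the moderated standard error (SE). All tests were two-sided. Replicates are called biological in the labels, without saying how the cultures were separated, so p-values measure the spread between these samples. The number of arrays limits the precision. The smallest p of an exact permutation test of 4 arrays against 4 is 0.0286.

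A background level was set at the 95th percentile of the mean levels of 17 measured genes taken as silent in breast cells, and came to 5.94. The share of changed genes with neither group above this level is given in the results.

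Before the data were examined, 34 gene lists were fixed. They cover sterol and fatty acid metabolism, prenyl transfer, RhoA signalling, YAP/TAZ and SRF/MRTF targets, immediate early genes, chaperones and ubiquitin ligases, the proteasome, the cell cycle, histones, adhesion, matrix, TGF-beta targets, mesenchymal and epithelial markers, inflammatory, interferon and stress responses, hypoxia, NRF2 targets, lysosome, ribosome, oxidative phosphorylation, apoptosis, and markers of 4 other cell types. Each was tested against all other genes with camera from limma at its preset correlation between genes of 0.01, adjusted over the 34 lists. The same test with the correlation estimated per list, and fry, were alternatives fixed beforehand. With an estimated correlation, camera takes its degrees of freedom from the arrays instead of the genes. A call is then harder to reach even where genes are not correlated. Counts of members past the threshold are given over all probe sets and, after a second adjustment, adjusted over the list alone.

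The genes named in the results follow a rule fixed before the data were examined. It takes 9 measured genes whatever their result, the 10 largest differences in each direction among genes past the threshold whose arrays do not overlap between groups and with a group mean above background, and up to 2 members per direction of each list with the largest differences past the threshold. Further genes, in the closing section, were chosen after their values were seen, as stated there.

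The procedure was tested on simulated data: over 54613 probe sets with 100 changed by 0.5 and 100 by 1 on the log2 scale, it recovered 63% and 95% of them for soft against stiff, with 2 false calls. The simulated noise was independent between probe sets and few probe sets were changed, so these rates need not hold for the real arrays. Alternatives were a replicate block, 3 other scalings between arrays, filters on dim probe sets, another variance model, array weights, other thresholds, probe sets without shared probes, the mean of all probe sets of a gene, and leaving out each array. Added after seeing the data were fits with only stiff A and B or only stiff C and D as stiff arrays, fry on these fits and without soft A, stiff C or stiff D, camera with an estimated correlation there and after the filters on dim probe sets, and an exact permutation test of each list's mean per array.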

Results

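Gene expression was measured in MDA-MB-231 breast cancer cells kept for 2 days on a soft or a stiff substrate, with 4 arrays per substrate. The question, as far as the title states it, was how mechanical cues act through the mevalonate pathway and the small GTPase RhoA. Arrays correlated with each other at 0.9932 to 0.9982 over all probe sets, and no 2 arrays held identical values. The first principal component held 40.4% of the variance and separated soft from stiff. The second held 16.4% and separated stiff A and B from stiff C and D.

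Cells on the soft substrate had 2040 of 19775 genes (10.3%) changed, 868 higher and 1172 lower, most of them by little: the median change was 1.27-fold, and 25 genes changed at least 2-fold. At adjusted p under 0.01 the balance turned, with 319 higher and 284 lower. RHOB, a small GTPase related to RhoA, rose most, to 2.97-fold its level on stiff (log2 difference 1.57, SE 0.294, adjusted p = 0.00851). The aldo-keto reductases AKR1C1, AKR1C2 and AKR1C3 rose 2.58-fold, 2.42-fold and 2.35-fold. AKR1C1 and AKR1C2 were read by probe sets marked as holding shared probes, so which of this pair changed is uncertain. The AKR1C3 probe set carries no such mark, though these paralogs share sequence. CYP1B1, a xenobiotic-metabolising cytochrome, rose 2.57-fold, the actin-severing protein gelsolin (GSN) 2.33-fold, the secreted proteins AGR2 and TFF1 2.37-fold and 2.17-fold, the glucocorticoid-induced TSC22D3 2.27-fold and the collagen COL6A1 2.16-fold. The phosphodiesterase PDE1C was 2.37-fold higher on stiff, followed by KISS1 (2.22-fold), the cytokine IL11 (2.18-fold), RGS7 (2.15-fold), the cohesin acetyltransferase ESCO2 (2.09-fold) and the RNA-binding protein RBM24 (2.08-fold). MYCT1, the cadherin FAT3, the chemokine receptor CXCR4 and the vitamin D hydroxylase CYP24A1 also fell on soft, with stiff over soft ratios of 2.08, 2.05, 2.02 and 2.

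COL6A1 passed the threshold at 3 of its 8 probe sets, by 1.11, 0.508 and 0.288. Others of its probe sets above background differed by 0.363 (adjusted p = 0.0725) and 0.025 (adjusted p = 0.906). RHOB rested on 1 of its 5 probe sets, the others lying under the background level of 5.94. Its difference was 2.22 against stiff A and B alone and 0.92 against stiff C and D alone; that of CYP1B1 was 1.82 and 0.90, and that of TSC22D3 1.79 and 0.57, the last no longer past the threshold (adjusted p = 0.0915). FAT3 differed by -1.40 and -0.67, the latter not past the threshold (adjusted p = 0.103), MYCT1 by -0.73, not past it against stiff A and B (adjusted p = 0.0597), and -1.38, and AGR2 by 0.87 and 1.62. Arrays of the 2 groups did not overlap for 3944 genes (19.9%), where chance gives 2.86%. Of the changed genes, 98 had neither group above background, and of the 1336 with several probe sets, 26 had another probe set called in the opposite direction.

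**Figure D1:**
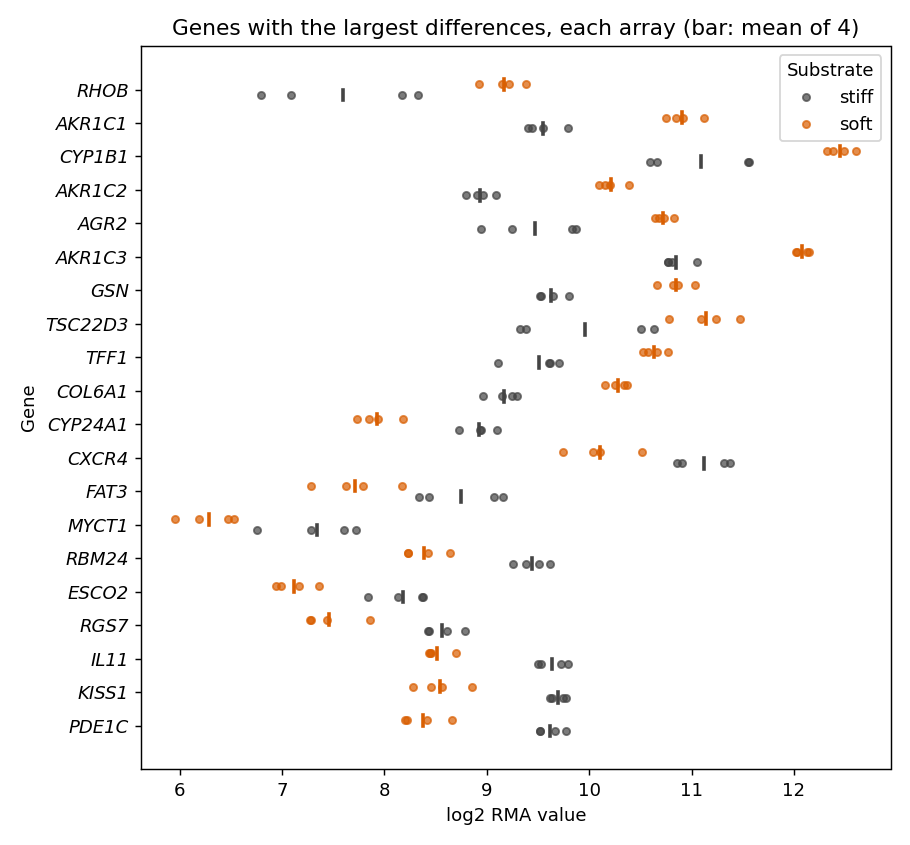
Log2 RMA values (x axis) of the 20 named genes with the largest differences (y axis) on each stiff (grey) and soft (orange) array, with a bar at the mean of 4. Soft and stiff arrays do not overlap for any gene shown; RHOB on stiff ranges from 6.8 to 8.33.

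YAP/TAZ targets are genes transcribed with the mechanosensitive coactivators YAP and TAZ. Of 21 measured, 11 were lower on soft, none higher and 10 not past the threshold (adjusted over the list alone, 14 lower and 2 higher). ANKRD1 fell by 0.65 (SE 0.0875, adjusted p = 0.00162), TGFB2 by 0.64 (SE 0.0764), CCN2 by 0.57 (SE 0.0734) and CCN1 by 0.42 (SE 0.0733) on the log2 scale. The list median was -0.24 (camera adjusted p = 1.84e-07, and adjusted p = 0.214 with an estimated correlation). List means did not overlap between the groups, at 0.119 to 0.156 on stiff and -0.181 to -0.0714 on soft arrays. The mean difference was -0.288 against stiff A and B alone and -0.273 against stiff C and D alone, with 9 members lower in each.

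Of 29 G2/M and mitosis genes 17 were lower on soft, none higher and 12 not past the threshold (28 lower adjusted over the list alone), with HMMR at -0.68 (SE 0.122, adjusted p = 0.00697) and the condensin subunit NCAPH at -0.52 (SE 0.089). Their median was -0.34 (camera adjusted p = 3.42e-15, and adjusted p = 0.392 with an estimated correlation). Of 26 G1/S and DNA replication genes 13 were lower, none higher and 13 not past the threshold (19 lower adjusted over the list alone), with the licensing factor CDT1 at -0.59 (SE 0.0782) and MCM10 at -0.53 (SE 0.106). Their median was -0.29 (camera adjusted p = 1.55e-10, and adjusted p = 0.392 with an estimated correlation). The stiff arrays differed here: the mean difference of the G2/M list was -0.426 against stiff A and B alone, with 17 members lower, and -0.255 against stiff C and D alone, with 0 past the threshold. For the G1/S list these were -0.346 with 8 lower, and -0.232 with 2 lower. Among 10 replication-dependent histone genes H2BC21 rose by 0.39 (from 5.695 to 6.085) and H1-4 fell by 0.43 (from 6.285 to 5.8575). Both lay near the background level of 5.94. The list median was -0.0138, its mean 0.0138 and its test pointed down (adjusted p = 0.859, with 1 higher and 1 lower adjusted over the list alone). That mean joins opposite signs. It was 0.172 against stiff A and B alone (fry adjusted p = 0.0291, and camera adjusted p = 0.356 with an estimated correlation). Against stiff C and D alone it was -0.145 (fry adjusted p = 0.0656), and camera called the list there (adjusted p = 0.0426, and adjusted p = 0.311 with an estimated correlation).

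**Figure D2:**
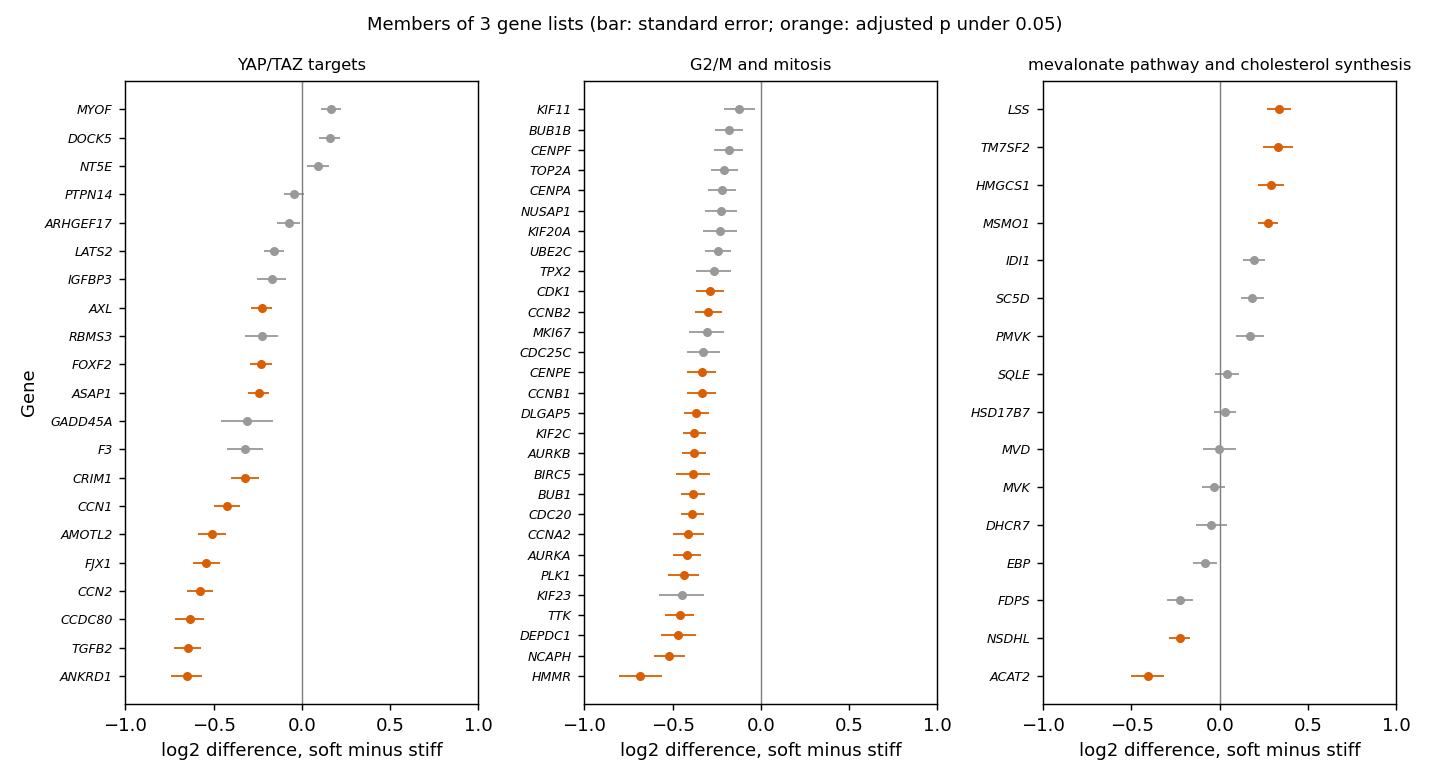
Log2 difference, soft minus stiff (x axis), with its standard error for each measured member (y axis) of the YAP/TAZ target, G2/M and mevalonate lists; orange marks adjusted p under 0.05. The called YAP/TAZ and G2/M members all lie below 0, whereas 4 called mevalonate genes lie above 0 and 2 below.

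The mevalonate pathway and cholesterol synthesis genes moved in both directions. Of 16 measured, 4 were higher, 2 lower and 10 not past the threshold (6 and 3 adjusted over the list alone). Lanosterol synthase (LSS) rose by 0.34 (SE 0.0676, adjusted p = 0.0119) and the sterol reductase TM7SF2 by 0.33 (SE 0.0839), while ACAT2 fell by 0.41 (SE 0.0943) and NSDHL by 0.23 (SE 0.0591). The list median was 0.0363 (camera adjusted p = 0.299). Its mean was 0.0131 against stiff A and B alone (fry adjusted p = 0.588) and 0.09 against stiff C and D alone (fry adjusted p = 0.0185), where camera did not call it (adjusted p = 0.111, and adjusted p = 0.311 with an estimated correlation). Of 10 SREBP2-regulated uptake and feedback genes 2 were higher, INSIG1 by 0.36 and SREBF2 by 0.29, and TMEM97 was lower by 0.50 (adjusted p = 0.362 for the list, with 2 and 2 adjusted over the list alone). Of 13 fatty acid synthesis genes 5 were higher and 2 lower (5 and 3 adjusted over the list alone; adjusted p = 0.299); the desaturase SCD rose by 0.63 (SE 0.102) and SREBF1 by 0.35, and GPAM and ELOVL6 fell by 0.34 and 0.30. Against stiff C and D alone this list was called (mean 0.157 above that of other genes, adjusted p = 0.0171, and adjusted p = 0.311 with an estimated correlation). Of 7 sterol efflux genes 1 was higher, SMPDL3A by 0.27 (4 adjusted over the list alone; median 0.22, adjusted p = 0.0361, and adjusted p = 0.329 with an estimated correlation). This list lost its call without soft C (adjusted p = 0.0553) or soft D (0.0821), with the mean of all probe sets (0.117), and against stiff A and B alone (0.066).

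RHOA itself differed by 0.19 (SE 0.0554, adjusted p = 0.0556), while another of its probe sets rose by 0.35 (adjusted p = 0.00721). It passed the threshold with cyclic loess (adjusted p = 0.0326), with the trended, robust variance model (0.00133) and with the mean of its probe sets (0.0283). Among 23 RhoA signalling and contractility genes 2 were higher, RHOB and RHOC (0.33), and 2 lower, the formin DIAPH3 (-0.46) and the cofilin kinase LIMK2 (-0.24), with 5 higher and 4 lower adjusted over the list alone. The median was -0.02, the mean 0.0515 and the test pointed up (adjusted p = 0.915). Against stiff C and D alone the mean was 0.0895 (fry adjusted p = 0.0139, camera adjusted p = 0.195, and 0.334 with an estimated correlation), against stiff A and B alone 0.0136 (fry adjusted p = 0.265). Of 12 prenyl transfer genes GGPS1, which makes geranylgeranyl diphosphate, rose by 0.40 (SE 0.0711), and CHML and PDSS1 fell by 0.39 and 0.36 (adjusted p = 0.316, with 1 and 2 adjusted over the list alone). The mean of this list was -0.103 against stiff C and D alone (fry adjusted p = 0.00691, camera adjusted p = 0.0704, and 0.311 with an estimated correlation) and -0.00396 against stiff A and B alone (fry adjusted p = 0.317). Of 16 SRF/MRTF targets TGFB1I1 and ACTB rose by 0.33 and 0.26, and TPM4 was lower by 0.42 at 1 probe set and higher by 0.45 at another one, under background (adjusted p = 0.362, with 4 and 2 adjusted over the list alone). Other TPM4 probe sets near the level of the one that fell differed by 0.01 (adjusted p = 0.96) and 0.07 (adjusted p = 0.632).

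Of 18 chaperones and ubiquitin ligases only the deacetylase HDAC6 passed the threshold, at 0.23 (SE 0.0598, adjusted p = 0.0389, with none adjusted over the list alone). Its other probe sets differed by -0.20 (adjusted p = 0.291) and 0.01 (adjusted p = 0.954). MDM2 differed by -0.15 (adjusted p = 0.325), though another of its probe sets fell by 0.27 (adjusted p = 0.0176). STUB1 differed by 0.02 (adjusted p = 0.885), HSP90AA1 by -0.06 (adjusted p = 0.629) and DNAJA1 by -0.15 (adjusted p = 0.217). The list median was -0.0975 (camera adjusted p = 0.028, and adjusted p = 0.403 with an estimated correlation), and the call was lost without stiff C (adjusted p = 0.053), soft A (0.057) or soft B (0.0512), after repeated quantile normalization (0.102) or cyclic loess (0.143), above background (0.109) or the median level (0.103), with the mean of all probe sets (0.0962), and against stiff A and B alone (0.0699). Of 27 proteasome subunits PSMC6 and PSMD2 fell by 0.21 and 0.20 (list adjusted p = 0.483, with 2 adjusted over the list alone).

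Of 25 integrin and focal adhesion genes 5 were higher, none lower and 20 not past the threshold (7 higher adjusted over the list alone), with ITGB4 up by 0.90 (SE 0.0981, adjusted p = 0.000583) and ITGA1 by 0.52 (SE 0.0909). The median was 0.11 (camera adjusted p = 0.00772, and adjusted p = 0.329 with an estimated correlation). Of 24 matrix protease and crosslinking genes 5 were higher (7 higher and 1 lower adjusted over the list alone), led by the protease inhibitors TIMP1 (0.86, SE 0.0957) and TIMP3 (0.47). That list's call (adjusted p = 0.0361, and adjusted p = 0.435 with an estimated correlation) was lost without stiff C (0.0774), stiff D (0.069), soft A (0.0576) or soft B (0.0512), and against stiff A and B alone (0.303). Of 25 collagens and matrix proteins COL6A1 rose and 3 fell, COL8A1 by 0.69 and COL12A1 by 0.59 among them (adjusted p = 0.965, with 2 and 3 adjusted over the list alone). Of 14 mesenchymal markers S100A4 rose by 0.53 and SNAI2 fell by 0.51 (adjusted p = 0.573, with 1 and 1 adjusted over the list alone). Of 15 epithelial markers CLDN7 and KRT19 each rose by 0.35 (adjusted p = 0.272, with 2 adjusted over the list alone). Of 14 TGF-beta/SMAD targets BHLHE40 rose by 0.64 (adjusted p = 0.299, with 4 higher and 1 lower adjusted over the list alone). BHLHE40 differed by 0.947 against stiff A and B alone and by 0.327 against stiff C and D alone, the latter not past the threshold. It kept its call in 12 of 17 alternative settings. The TGF-beta list was called against stiff C and D alone (adjusted p = 0.0426, and adjusted p = 0.311 with an estimated correlation) and, with all arrays, by fry (0.0278), as was the epithelial list (0.0194). With all arrays, camera with an estimated correlation called neither of them (adjusted p = 0.435 for both).

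Of 15 NRF2 targets 5 were higher, none lower and 10 not past the threshold (5 adjusted over the list alone; median 0.21, adjusted p = 9.59e-06, and adjusted p = 0.392 with an estimated correlation); AKR1C1 and AKR1C3, which share sequence, are 2 of the 5. The list mean was 0.445 with 8 members higher against stiff A and B alone, and 0.231 with 2 higher against stiff C and D alone. Of 18 lysosome and autophagy genes 5 were higher and none lower (9 adjusted over the list alone), cathepsins CTSD by 0.72 (SE 0.118) and CTSB by 0.43 (SE 0.0737) most (adjusted p = 0.000217, and adjusted p = 0.329 with an estimated correlation). Of 23 hypoxia and glycolysis genes 4 were higher, NDRG1 by 0.79 (SE 0.0918) and ANKRD37 by 0.47, and ADM fell by 0.58 (11 and 1 adjusted over the list alone; adjusted p = 3.63e-05, and adjusted p = 0.295 with an estimated correlation). ADM differed by -0.288 against stiff A and B alone, not past the threshold, and by -0.878 against stiff C and D alone. It kept its call in 10 of 17 alternative settings. Of 23 interferon response genes 9 were higher, IFI27 by 0.56 and OAS2 by 0.56 most, and IFIT2 fell by 0.48 (11 and 1 adjusted over the list alone; adjusted p = 0.000682, and adjusted p = 0.392 with an estimated correlation); against stiff A and B alone the list missed the threshold (adjusted p = 0.0628). None of 22 ribosomal protein genes passed the threshold (none adjusted over the list alone), yet the list lay lower, with median -0.0662 (adjusted p = 0.00982, and adjusted p = 0.435 with an estimated correlation). Its call was lost after repeated quantile normalization (adjusted p = 0.0952) and cyclic loess (0.195).

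The remaining lists were not called with all arrays. KLF4 rose by 0.49, the 1 change among 18 immediate early genes (adjusted p = 0.186, with none adjusted over the list alone), and VLDLR and HERPUD1 rose by 0.64 and 0.34 among 21 unfolded protein and integrated stress response genes (adjusted p = 0.232, with 2 adjusted over the list alone). Both lists depended on the stiff arrays. Against stiff A and B alone each had a mean 0.394 above that of other genes and was called (adjusted p = 2.21e-10 and 1.17e-08, and adjusted p = 0.19 for both with an estimated correlation). They were also called at the preset correlation without stiff C (0.00845 and 0.0182) or stiff D (0.0125 and 0.0187), but not with an estimated correlation (adjusted p = 0.694 and 0.585, and 0.646 and 0.632). Against stiff C and D alone these differences were -0.18 (adjusted p = 0.0106, and adjusted p = 0.311 with an estimated correlation) and -0.0854 (adjusted p = 0.0704). Of 19 inflammatory genes NFKBIA rose by 0.43 and IL11 fell (adjusted p = 0.547, with 2 and 1 adjusted over the list alone). ATP5MC1 fell by 0.22 among 21 oxidative phosphorylation genes (adjusted p = 0.604, with none adjusted over the list alone), and of 15 apoptosis regulators BMF rose by 0.43 and BCL2 and BAX fell by 0.49 and 0.22 (adjusted p = 0.409, with 2 and 3 adjusted over the list alone).

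With all probe sets, camera called no list of markers of other cell types. Of 12 luminal breast epithelium markers TFF1 and KRT19 rose (median 0.07, adjusted p = 0.137, with 3 adjusted over the list alone). The luminal list was called above background (mean 0.297 above that of other genes, adjusted p = 0.0493), above the median level (0.296, adjusted p = 0.0498) and with fry (adjusted p = 0.0135). With an estimated correlation the first 2 calls are lost (adjusted p = 0.344 and 0.348), and with all probe sets camera then gives an adjusted p of 0.392. The endothelial marker PECAM1 rose by 0.49, 1 of 8 (adjusted p = 0.859, with 1 adjusted over the list alone), and no marker changed among 10 fibroblast (adjusted p = 0.604) and 9 leukocyte genes (adjusted p = 0.409), with none adjusted over the list alone. Neither group lay above background for 5 of the 8 endothelial, 8 of the 10 fibroblast and 6 of the 9 leukocyte markers. Unchanged values at such dim probe sets say little. The 3' minus 5' signal rises as RNA integrity falls. It differed between soft and stiff by -0.0475 for ACTB (exact permutation p = 0.571) and -0.0275 for GAPDH (exact permutation p = 0.371).

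Among the genes named, those that kept their call in 8 or fewer of 17 alternative settings were BAX and LIMK2 (3), PSMC6 and PSMD2 (4), ATP5MC1 and HDAC6 (5), KLF4 (6), H2BC21 and NSDHL (7), and INSIG1 and SMPDL3A (8). None of the 12 called lists kept its call with an estimated correlation. That test also has fewer degrees of freedom, so correlation between genes is not the only reason. For sterol efflux the estimate was -0.0155, below the preset 0.01, yet the unadjusted camera p rose from 0.0121 to 0.0415. The lost calls therefore do not by themselves show that correlated genes made the calls. With fry on all arrays, which does not compare a list with other genes, all 12 had adjusted p under 0.05. These ranged from 0.000915 (YAP/TAZ targets) to 0.0459 (matrix proteases and crosslinking). In an exact permutation test of list means per array, added after seeing the data, 14 of the 34 lists had no overlap between the groups, each at the smallest possible p of 0.0286, which adjusts to 0.0695. This test could hardly call any list, since most of the 34 would have to reach that p, so the absence of calls decides nothing.

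**Figure D3:**
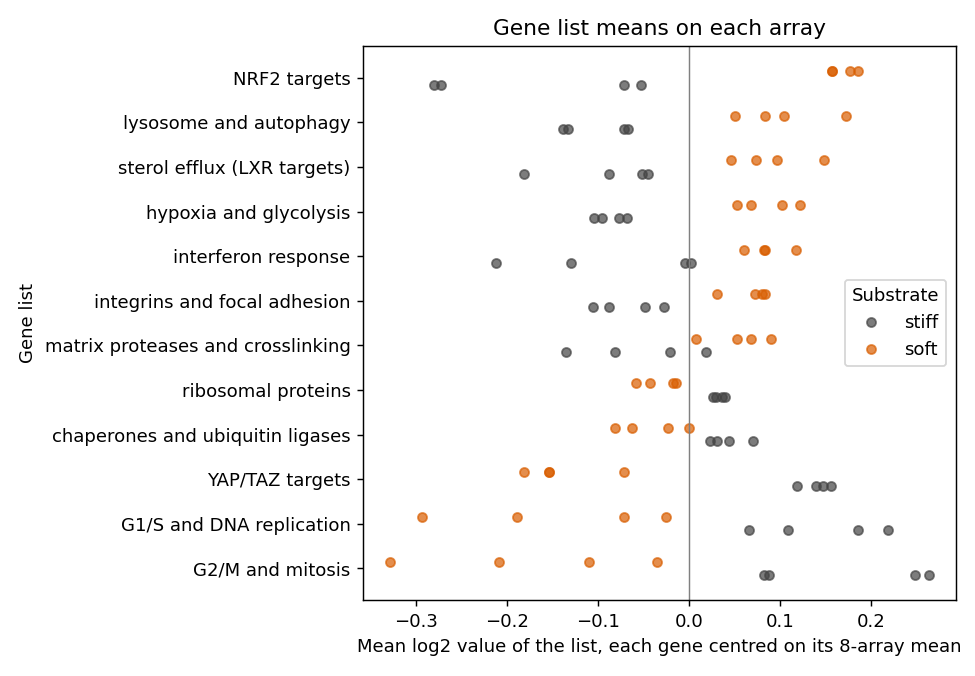
Mean log2 value of the 12 called gene lists (y axis) on each stiff (grey) and soft (orange) array, with each gene centred on its mean over 8 arrays (x axis). Soft and stiff arrays are apart for each list shown except matrix proteases and crosslinking (stiff up to 0.0183, soft from 0.00792).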

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

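In 12 of 252 groups of 4 arrays, for the named genes, list means and RNA integrity signals, a single array stood apart from the other 3, with its gap to them given as a share of the range. Chance flags about 1 in 20 groups, here 12.6, so their number is what chance gives. On stiff arrays these were AKR1C3 (0.857, D high), BMF (0.947, A low), HDAC6 (0.833, C high), STUB1 (0.833, C low), TFF1 (0.833, C low) and the fibroblast list mean (0.867, A high). On soft arrays they were HMMR (0.895, A low), IL11 (0.923, C high), PECAM1 (0.85, A high), the RhoA list mean (0.92, A low), the luminal list mean (0.833, A high) and BAX (share of 1, A low), where the 4 values differ by a single rounding step, 9.33 against 9.34.

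Tests chosen only after their result was seen are the luminal cell test, the RNA integrity test, the second reading of shared probes, the distance of levels from background, the balanced splits and the fry test below. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, called as many probe sets (5061 against 0 at most elsewhere), genes (2040 against 0) and lists (12 against 11). This argues against chance for the counts of probe sets and genes at the smallest p such splits allow, 0.0286, but does not exclude it. The size of the gap adds little, since the other splits hold the soft-stiff difference in their spread, which lowers their calls. For lists the margin was 1. Of the 18 splits with 2 stiff and 2 soft arrays on each side, the 6 that set stiff A and B against stiff C and D called 4 to 11 lists and the other 12 called 0 to 3, so at the preset correlation of 0.01 that difference between stiff arrays calls lists too.

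Single probe sets moved apart from the rest of their gene. Compared were 16026 probe sets above background in 5871 genes with several. Of these, 27 in 20 genes differed at least 2-fold in their change from the others of their gene. Examples, chosen after their values were seen, are PSME4 (-1.92), CDC27 (-1.46), MBNL2 (-1.25) and FER (1.21). Only 1 of the 35 splits, the real one, gave as many (27 against 0), which argues against array noise at the smallest p such splits allow, 0.0286. The 0 elsewhere adds little, since mixed splits average out any soft-stiff difference. Probe sets marked as shared between transcripts were not enriched among the 27 (odds ratio 0.633, 95% interval 0.25 to 1.48), but these include still partners of moving probe sets, and among the 20 that themselves moved more than their gene's others the odds ratio of 0.844 has an interval of 0.299 to 2.25, so cross-hybridisation stays open. That 100% lay above background follows from comparing only such probe sets. Their median level lay 2.51 above it (95% interval 1.72 to 3.95), so most of the 27 were not close to background, though 4 lay within 1. The interval counts the still partners too. The distance of the other probe sets compared was not computed, so whether the 27 were dimmer than those is not known. Different transcript forms are a candidate explanation for the 27, which probe positions, not used here, would be needed to test.

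TFF1, AGR2 and KRT19, made by luminal breast cells, rose on soft. Cells of that type would bring their other abundant transcripts, yet the median difference of 9 other luminal markers was 0.0475 (95% bootstrap interval -0.0575 to 0.295), below the 0.35 by which KRT19 rose, and CDH1 and FOXA1 lay under background on both substrates. The median is a weak test, since the 0.35 comes from 1 of the 3 genes to be explained. KRT18, KRT8 and XBP1 were also already at 13.1, 11.13 and 9.6 on stiff, where added cells need not raise them. TFF3 differed by 0.64 (adjusted p = 0.0605) and MUC1 by 0.3 (adjusted p = 0.283), and the other markers by -0.08 (GATA3) to 0.1 (XBP1). A growth state that also lowers cell cycle genes may remain: within groups over the 8 arrays, the mean of the 3 genes and that of the cell cycle lists had r = 0.328 (95% interval -0.565 to 0.867, exact permutation p = 0.422) and rho = 0.238 (exact permutation p = 0.569), with r = -0.0576 without the 2 arrays farthest out, so the inverse relation this needs was not seen but lies within the interval. The split between stiff arrays enters this relation. AGR2 was 9.87 and 9.83 on stiff A and B against 8.94 and 9.25 on C and D. The G2/M list mean was 0.248 and 0.263 against 0.0819 and 0.0878. Since that split alone could give a positive r, the relation cannot decide the question. A response of the cells to the substrate stays open, as untested.

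If a batch of arrays carried the lower cell cycle lists on soft, the G2/M list would lose its place with only stiff C and D, or without soft A. Its adjusted p at the preset correlation was at most 9.28e-09 in these fits, but that decides nothing, since its estimated correlation is 0.782. With fry the higher p, not adjusted over lists, was 0.0514, with only stiff C and D, where the mean difference was -0.255 against -0.426 with only stiff A and B, so a part carried by stiff A and B stays open. Soft arrays spread too. The G2/M list mean was -0.328 on soft A, which had the lowest array weight (0.559), and -0.0346 on soft C. Without soft A the mean difference was -0.288, with 12 members lower. Lower RNA integrity on soft would raise the 3' minus 5' signal there. The signal was instead lower on soft for both ACTB (-0.0475) and GAPDH (-0.0275). Both differences lay within the spread of the arrays, so lower integrity on soft was not seen but is not excluded. A response to the substrate stays open, as untested.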

How the results depend on the processing

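Fits with only some stiff arrays, fry and the estimated correlation on these fits, and the permutation of list means were chosen after seeing the data. The count of 2040 genes fell to 25 at 2-fold, 603 at adjusted p under 0.01, 1104 against stiff A and B and 835 against stiff C and D, and rose to 3064 above background, where fewer probe sets are tested; 5061 probe sets fell to 69, 1663, 2659 and 2188, and to 2900 without shared probe sets. Without 1 array, genes ranged from 1092 (stiff B) to 2040 (soft C) and probe sets from 2851 to 5080; genes numbered 1322 without stiff C, 1351 without stiff D, 1321 without soft A, 1355 without soft B and 1257 without soft D. The share of changed genes that were higher, 42.5%, was 36.8% after centring each array on its median, 47.5% with cyclic loess, 52.9% at adjusted p under 0.01, 60% at 2-fold, 52.4% against stiff A and B and 53.7% against stiff C and D, and 50.1% of changed probe sets were higher. The replicate letters do not pair the samples (correlations of deviations 0.122, -0.118, 0.0516 and -0.0447 for A to D, and not every array correlates best with its own letter); the replicate block gave 1452 genes, 3937 probe sets and 12 lists. The 12 lists became 0 with an estimated correlation and 0 by permutation of list means, where 14 lists reached the smallest p, which then adjusts to 0.0695; YAP/TAZ, both cell cycle, integrin, hypoxia, NRF2 and lysosome lists kept their camera call in all other settings. Of 85 genes past the threshold that the naming rule took, 28 lost it without 1 array, 16 with the replicate block, 26 against stiff A and B, 35 against stiff C and D and 37 in none of the 17 settings run for single genes, which leave out the thresholds and the filters on probe sets. List means relative to other genes that changed sign, none called in the main analysis, were, after repeated quantile normalization and cyclic loess, the proteasome (0.00237 and 0.00753), oxidative phosphorylation (0.0075 and 0.014) and endothelial (-0.0103 and -0.0126) lists; above background and above the median level, collagens (0.00449 and 0.00361), mesenchymal (-0.00115 and -0.00202) and oxidative phosphorylation (0.00115 and 0.000274); against stiff A and B, SREBP2 (-0.0191), prenyl (0.00197) and endothelial (-0.0816); and against stiff C and D, immediate early (-0.18, adjusted p = 0.0106), a list not named here (-0.00974), histones (-0.151, adjusted p = 0.0426), collagens (0.026), mesenchymal (-0.0065), inflammatory (-0.0534), stress response (-0.0854) and oxidative phosphorylation (0.00255), the 2 calls among these being lost with an estimated correlation (adjusted p = 0.311 for both). Without 1 array, histones ranged from -0.0432 to 0.0913, inflammatory from -0.0067 to 0.0598, endothelial from -0.0251 to 0.0424 and STUB1 from -0.00583 to 0.0442. TPM4 turned to 0.038 with the mean of its probe sets. The cause was not tested. Probe sets near background limit what can be called.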

Other observations

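Gene families grouped by symbol stem were tested after the data had been seen, 137 families with at least 10 genes above background. No family is called with an estimated correlation. Of the mitochondrial ribosomal proteins, 7 of 49 MRPL genes (median -0.135) and 6 of 27 MRPS genes (median -0.165) were lower, none higher and the others not past the threshold. RNA polymerase subunits (POLR, 13 of 31 lower), nucleoporins (NUP, 7 of 23 lower) and the mitochondrial import genes (TIMM, 7 of 14 lower) likewise had none higher. The KLF transcription factors (6 of 13 higher, median 0.26) and the KDM histone demethylases (6 of 16 higher, median 0.178) went the other way. Camera's adjusted p at the preset correlation was 0.000189 for MRPL and 0.0103 for KLF; with an estimated correlation it was 0.713 for MRPL and 0.701 for KLF.

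Stiff arrays A and B lay apart from C and D in the means of several lists. No test compared them alone, but the balanced splits that set them against each other called 4 to 11 lists at the preset correlation. The mean of the immediate early list was -0.323 and -0.344 on A and B, 0.234 and 0.219 on C and D, and 0.00347 to 0.106 on soft arrays. The unfolded protein and integrated stress response list had -0.299 and -0.322 on A and B, 0.146 and 0.166 on C and D, and 0.0165 to 0.133 on soft arrays. Histones had -0.154 and -0.176 on A and B, and 0.211 and 0.0919 on C and D, while the interferon list went the other way, with -0.00413 and 0.00239 against -0.212 and -0.13. These lists were picked after the values were seen, and the labels give no batch.

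Probe sets used for no gene, because they have no symbol or several, were also changed, 529 higher and 364 lower of 13522, the largest differences being 1.68 and 1.19 upward and -1.65 and -1.29 downward among those above background with no overlap between groups.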
